A study of Mus musculus with 18 samples.

How the data were processed

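RNA of mouse embryos without the head was sequenced in 18 libraries that fall into 6 groups of 3. At E9.5 the groups were wild type and homozygous Del(i9-13), and at E10.5 they were wild type, Del(i9-13), Del(i9-13):Hoxb13hd and Hoxb13hd. Del(i9-13) is a mutation of the HoxB cluster, per the labels, and was read as a deletion in the interval between Hoxb9 and Hoxb13. What the letters hd stand for is not given in the sources used here. The E9.5 libraries were poly(A)-enriched and the E10.5 libraries ribo-depleted, both with stranded kits, per the labels' protocols, so that stage and library type coincide. Levels were set against each other between stages in a single place, the direction of E9.5 minus E10.5 in the Del(i9-13) libraries, where library type may contribute. Groups were taken from the sample titles, every column of both tables was assigned to a sample, and 0 columns were left unused.

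The deposited count table held whole-number read counts per Ensembl gene for 55141 genes. Per the submitters' processing notes, reads were trimmed with cutadapt 1.18 and aligned to mm10 with STAR 2.7.10a. The version of the counting program, its strand setting and its annotation are not given in the sources used here, so counts of pseudogenes, close paralogs and overlapping or antisense genes are uncertain. The deposited FPKM table held FPKM (fragments per kilobase of transcript, scaled to the mapped fragments) for 55138 genes, computed by the authors with Cufflinks 2.2.1, per the submitters' processing notes. Mir451a, Mir873a and Mir30f were in the count table alone. Coordinates are mm10 and came from the FPKM table. Of its genes, 54887 were in GENCODE M21, 51299 of them with the same coordinates, and gene types came from that annotation.

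Totals ran from 19.3 to 35.9 M counts per library. Replicates varied beyond sampling noise, with a chi-square per degree of freedom of 9.40 to 49.6 across groups, so that the spread between libraries, not depth, limited the precision of well-expressed genes. Exact 95% intervals of ratios and the floor of 3 counts over a group cover counting error only.

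Counts were analysed in R 4.3.3 with edgeR 4.0.16. Low counts were removed with filterByExpr (minimum count 10, minimum total 15), libraries were scaled with TMM, and a robust quasi-likelihood model was fitted separately for the 6 E9.5 libraries and the 12 E10.5 libraries. Genes passed at an adjusted p (Benjamini-Hochberg over all genes tested) of 0.05, and are called below. Levels in CPM are counts scaled to library size with TMM factors and are given as mean ± SD of 3 libraries. Log2 values are fitted log2 fold changes with their standard error (SE). An interaction term asked whether the deletion acted differently with and without hd at E10.5. A fit of E9.5 and E10.5 wild type and Del(i9-13) libraries asked whether the deletion effect differed between stages.

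Gene groups were tested with camera (limma 3.58.1, preset correlation 0.01), adjusted over 29 lists of tissue markers and pathways within each comparison, with an estimated correlation and with fry as alternatives. List members were also adjusted over the list alone. A list of 24 sterol synthesis genes was chosen after the data were seen, and its tests are not independent evidence. For Hoxb13, exact two-sided permutation tests of log2 CPM (pseudocount 0.1) were run, whose smallest possible p for 3 against 3 is 0.1. Genes called near Hoxb13 were counted within 500 kb and tested with Fisher's exact test. HoxB genes and those in the deleted interval (Gm53 and Mir196a-1) were kept out of the window and counted with the genes outside it. Genes in the deleted interval were left out of the overlaps of deletion effects. Overlaps of calls were compared with the number expected if the comparisons were independent and, for those that share the wild type libraries, covariance, correlation and signs of the effects with 20 simulations without any effect.

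The genes named per comparison were fixed by a rule. It took Hoxb13, the other HoxB genes and Hoxa13, Hoxc13 and Hoxd13. It then took up to 10 called genes each way with the largest log2 change, a mean CPM of at least 1 in either group and no overlap between the libraries of the groups. It left out sex-linked marker genes and symbols without a name of their own. From each list that passed camera it took up to 4 members with the smallest p. A few genes are not reported here. Gm53 and Mir196a-1, which lie between Hoxb9 and Hoxb13, were added after the data were seen, as were Tbx4, Pitx1 and Tbx5 and the members of overlaps between comparisons.

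The groups, comparisons, thresholds, 29 lists, naming rule and most alternatives were chosen before the data were examined. These alternatives were RLE scaling, no filter, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0, limma on log2 FPKM with pseudocounts of 0.1 and 1 (FPKM of at least 1 in 3 libraries) or without the filter, and an absolute log2 change of at least 1. They also included leaving out chromosomes X, Y and M, a replicate block, fits of only the groups compared, windows of 200 kb and 1 Mb, an unadjusted p of 0.001 for overlaps, and leaving out each library. An Xist covariate, the removal of pseudogenes, and the removal of E10.5 Del(i9-13) replicate 2 were added after the data were seen.

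The models were tested on simulated counts with 200 genes changed by 1.5-, 2- or 4-fold. At E9.5, edgeR recovered 44.8%, 71.6% and 86.4% of these. For Del(i9-13) against wild type at E10.5 it recovered 38.8%, 64.2% and 90.9%, for Del(i9-13):Hoxb13hd against wild type 44.8%, 61.2% and 90.9%, and for Hoxb13hd against wild type 41.8%, 61.2% and 87.9%. For Del(i9-13) against Del(i9-13):Hoxb13hd it recovered 44.8%, 65.7% and 89.4%, and for Del(i9-13):Hoxb13hd against Hoxb13hd 43.3%, 73.1% and 84.8%. Unchanged genes made up 4.29% to 10% of the edgeR calls in these simulations. Among DESeq2 calls they made up 23.7% for E9.5 and 16.6% for E10.5 Del(i9-13) against wild type, and among limma calls 5.26% and 4%.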

Results

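Headless mouse embryos were profiled by RNA sequencing at E9.5 in wild type and Del(i9-13) and at E10.5 in wild type, Del(i9-13), Del(i9-13):Hoxb13hd and Hoxb13hd, with 3 libraries per group. The series title links insulation of Hoxb13, the most 5′ gene of the HoxB cluster, to the timing of tail formation. In the E9.5 libraries wild type totals were 35.9, 29.8 and 30.1 M counts and Del(i9-13) totals 34.6, 29.9 and 31.7 M. At E10.5 the totals were 21.9, 23.7 and 23.6 M in wild type, 24.2, 22.2 and 23.3 M in Del(i9-13), 22.6, 25.7 and 23.1 M in Del(i9-13):Hoxb13hd, and 21.6, 21.7 and 19.3 M in Hoxb13hd. The labels do not say whether a replicate is a single embryo or a pool. Xist and Y-linked genes differed between replicates in every group other than E9.5 Del(i9-13), so that in those groups the replicates are not all repeats of a single sample. The p-values measure the spread between these libraries. A number in parentheses after a gene is its log2 fold change, followed where given by its adjusted p. List members given as lying at a log2 value did not pass over all genes tested. For every gene named from the calls by size of change, all 3 libraries of one group lay above all 3 of the other.

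Hoxb13 (ENSMUSG00000049604, chromosome 11, 96194316 to 96197447, mm10) was low in wild type and higher in every library with the deletion. At E9.5 the wild type libraries held 4, 1 and 4 counts of Hoxb13 and the Del(i9-13) libraries 1300, 1299 and 1421. At E10.5 the wild type libraries held 25, 3 and 1 counts, Del(i9-13) 269, 130 and 288, Del(i9-13):Hoxb13hd 255, 307 and 228, and Hoxb13hd 0, 1 and 2. The level in Del(i9-13) was 42.0 ± 3.79 CPM at E9.5 against 0.0927 ± 0.0523 in wild type (log2 8.74, SE 0.21, adjusted p = 3.5e-07, n = 3 each), a ratio of counts of 445 (95% interval 234 to 974). At E10.5 it was 9.60 ± 3.29 CPM in Del(i9-13) (log2 4.49, SE 0.62, adjusted p = 0.0074) and 11.1 ± 1.06 in Del(i9-13):Hoxb13hd (log2 4.69, SE 0.62, adjusted p = 0.011), against 0.434 ± 0.607 in wild type. Against Hoxb13hd, at 0.0510 ± 0.0529 CPM, Del(i9-13):Hoxb13hd was higher by log2 7.67 (SE 0.86, adjusted p = 0.0032), a ratio of 227 (77.5 to 1104). Hoxb13 did not pass in Del(i9-13) against Del(i9-13):Hoxb13hd (log2 −0.20, SE 0.45, adjusted p = 0.87) or in Hoxb13hd against wild type (log2 −2.98, SE 1.33, adjusted p = 0.24; ratio 0.117, 0.0228 to 0.377). Exact two-sided permutation p were 0.1, the smallest possible, for E9.5 and for the 3 E10.5 comparisons with a call, 0.3 for Hoxb13hd against wild type and 0.7 for Del(i9-13) against Del(i9-13):Hoxb13hd. Wild type replicate 1 set the size of the E10.5 values, since without it log2 was 6.74 in Del(i9-13), 6.95 in Del(i9-13):Hoxb13hd and −0.72 in Hoxb13hd, each against wild type. Without wild type replicate 2 the call in Del(i9-13):Hoxb13hd was lost (log2 4.27, adjusted p = 0.07). Fits of only the groups compared lost the E10.5 calls against wild type (adjusted p = 0.19 and 0.067), as did a fit without a filter for Del(i9-13) and an Xist covariate for Del(i9-13):Hoxb13hd (0.053 each). Adjusted p over the alternatives ran from 9.2e-05 to 0.19 and from 1.3e-04 to 0.07.

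**Figure D1:**
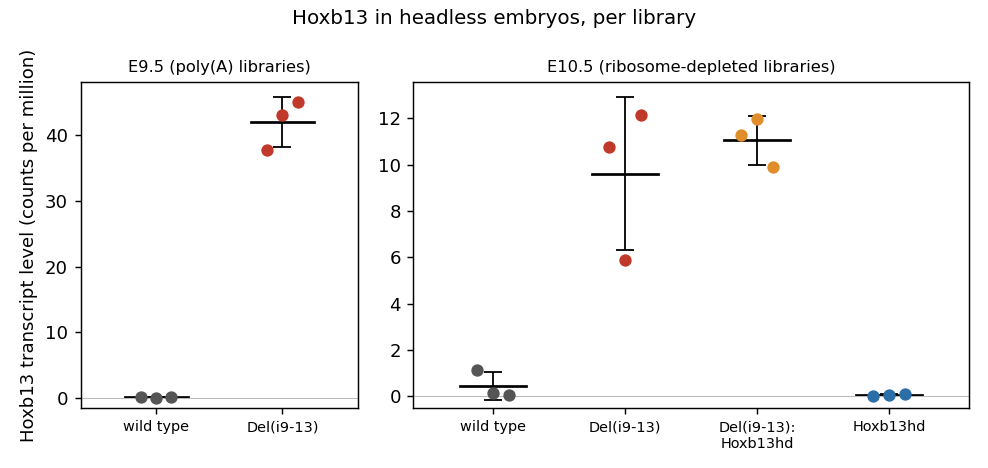
Hoxb13 level in CPM for each library (points) at E9.5 and E10.5, by genotype, with bars for the mean ± SD of 3 libraries. The deletion libraries lay at 42.0 CPM on average at E9.5 and at 9.60 and 11.1 CPM at E10.5, against 0.0927 to 0.434 CPM in wild type.

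Inside the deleted interval, the long noncoding gene Gm53 (ENSMUSG00000078706, chromosome 11, 96251105 to 96264868) lost its counts, which checks the labels of the deletion libraries. At E9.5 it had 3 counts over the Del(i9-13) group against 23.1 ± 8.59 CPM in wild type (ratio 0.00138, 0.000285 to 0.00405; adjusted p = 0.016). At E10.5 it had 0 counts over Del(i9-13) and over Del(i9-13):Hoxb13hd, at least 453-fold and 456-fold lower than the 19.3 ± 4.03 CPM of wild type against a floor of 3 counts over the group (adjusted p = 0.00026 and 0.00042). In Hoxb13hd it was at 45.4 ± 13.2 CPM (log2 1.23, SE 0.24, adjusted p = 0.045), a call that was lost when any library other than Hoxb13hd replicate 1 was left out (adjusted p up to 0.171 over the alternatives). The E9.5 call was lost without any 1 of the Del(i9-13) libraries (adjusted p up to 0.246). The microRNA gene Mir196a-1 did not pass at E9.5 (0.170 against 1.13 CPM, log2 −2.72, adjusted p = 0.055).

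Hoxb9 (ENSMUSG00000020875, chromosome 11, 96271457 to 96276595), the HoxB gene at the other end of the interval, fell in 3 of the 4 comparisons in which Hoxb13 rose. It was at 54.0 ± 4.74 CPM in E10.5 Del(i9-13) against 91.0 ± 8.38 in wild type (log2 −0.75, SE 0.11, adjusted p = 0.0043) and at 69.9 ± 3.13 in Del(i9-13):Hoxb13hd against 115 ± 17 in Hoxb13hd (log2 −0.71, SE 0.11, adjusted p = 0.0093). At E9.5 it was at 183 ± 6.11 against 247 ± 18.9 CPM (log2 −0.43, SE 0.06, adjusted p = 0.034), and in Del(i9-13):Hoxb13hd against wild type it did not pass (log2 −0.38, adjusted p = 0.17). The E9.5 call was lost when any library other than wild type replicate 3 was left out (adjusted p up to 0.216), and the call against Hoxb13hd without Hoxb13hd replicates 2 or 3 (up to 0.0531). The other HoxB genes did not pass against wild type in Del(i9-13), with log2 values from −0.24 (Hoxb7) to 0.28 (Hoxb5os) at E9.5 and from −0.39 (Hoxb1) to 0.38 (Hoxb7) at E10.5. Among the other group 13 genes, Hoxa13, Hoxc13 and Hoxd13 had log2 values of −0.31, −0.25 and −0.01 at E9.5 and −0.44, −0.65 and −0.00 at E10.5, all above the threshold (adjusted p of 0.5 and more). Without Del(i9-13) replicate 2 the E10.5 values were 0.09, −0.23 and 0.30, and Hoxc13 was lower still without Del(i9-13) replicate 1. Within 500 kb of Hoxb13, 14 genes other than HoxB genes and Gm53 were tested at E10.5. Of these, Ttll6 (chromosome 11, 96133786 to 96165451), a tubulin polyglutamylase, rose from 0.708 ± 0.21 CPM in wild type to 2.37 ± 0.171 in Del(i9-13) (log2 1.74, SE 0.27, adjusted p = 0.0082) and 2.43 ± 0.236 in Del(i9-13):Hoxb13hd (log2 1.78, adjusted p = 0.014). This call made up 7.14% of these neighbours, against 0.483% and 0.396% of all other genes tested, among which HoxB genes and Gm53 were counted (Fisher's exact p = 0.0663 and 0.0547). Fisher's exact test passed within 200 kb (p = 0.0337 and 0.0277) and within 1 Mb (7.1e-04 and 4.0e-04). At E9.5 and in Del(i9-13):Hoxb13hd against Hoxb13hd 0 of the 14 neighbours were called, with Ttll6 at log2 0.32 (0.716 against 0.587 CPM, adjusted p = 0.91) and 1.03 (2.43 against 1.19 CPM, adjusted p = 0.071). In Hoxb13hd against wild type Snf8, within 200 kb and named after its value was seen, was called higher (0.40, adjusted p = 0.019). Ttll6 was no longer called in Del(i9-13) without wild type replicate 2 and in Del(i9-13):Hoxb13hd without wild type replicates 1 or 2 or Del(i9-13):Hoxb13hd replicate 3 (adjusted p up to 0.158 and 0.146).

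**Figure D2:**
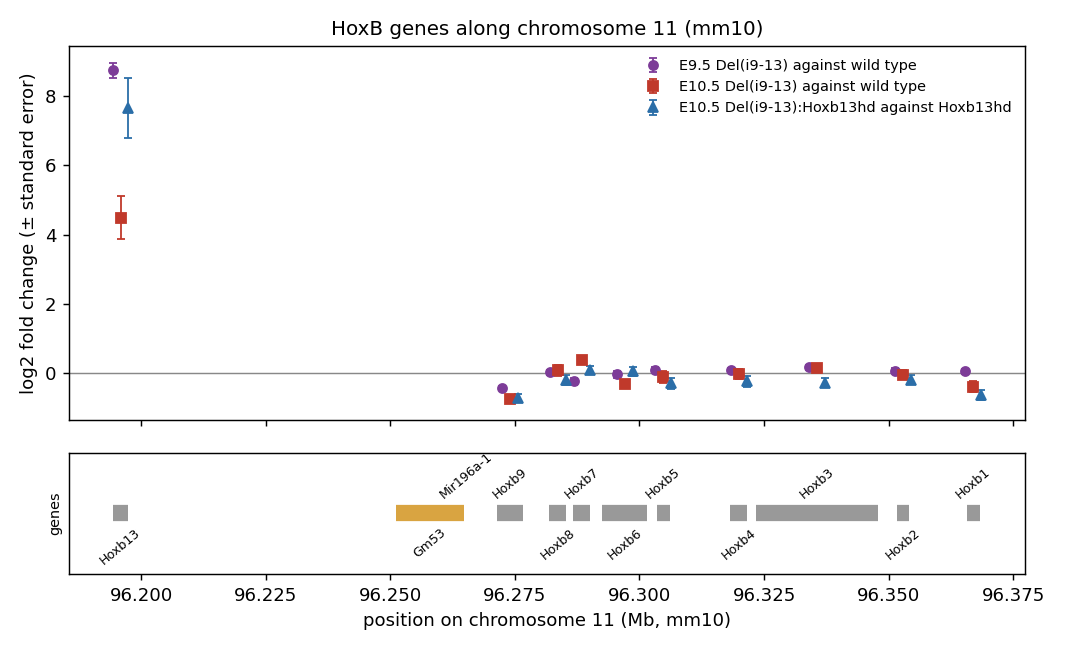
Top, log2 fold change ± SE of genes along chromosome 11 (mm10 position) for E9.5 Del(i9-13) against wild type (circles), E10.5 Del(i9-13) against wild type (squares) and E10.5 Del(i9-13):Hoxb13hd against Hoxb13hd (triangles), offset sideways for clarity; bottom, gene positions. Hoxb13 lies at 8.74, 4.49 and 7.67 and Hoxb9 at −0.43, −0.75 and −0.71.

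The E9.5 comparison asked what else changed in embryos with the deletion. Of 16041 genes tested, 58 passed, 15 higher and 43 lower than in wild type. Genes of sterol synthesis fell. Insig1, which holds back the processing of sterol regulatory factors, went from 66.2 ± 5.66 to 38.4 ± 2.13 CPM (log2 −0.78, SE 0.08, adjusted p = 0.0042), and the sterol reductase gene Tm7sf2 from 21.3 ± 0.734 to 12.2 ± 1.13 (log2 −0.80, adjusted p = 0.0096). Of 24 sterol genes, a list chosen after the data were seen, 16 were called lower and 23 had negative values, with a median log2 of −0.57. Also lower were Rprm, a cell cycle arrest gene (log2 −1.22, SE 0.12, adjusted p = 0.0051; 6.44 ± 0.802 against 15.0 ± 1.17 CPM), Scoc (−1.13), the rhomboid protease homolog Rhbdl3 (−0.94) and the zinc finger gene Zfp949 (−0.84). Higher were Ide, the insulin-degrading enzyme (0.54, adjusted p = 0.0037; 149 ± 3.87 against 103 ± 2.6 CPM), Arl5a (0.54, adjusted p = 0.0096) and Tma7 (0.63, adjusted p = 0.0065). The calls of the 9 genes named here held whichever library was left out. Over all alternatives other than a minimum log2 change of 1, Rprm and Insig1 kept theirs, and the others reached an adjusted p of up to 0.448 (Zfp949).

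Further called genes at E9.5 depended on single libraries. The neural adhesion gene Chl1 was higher (10.9 ± 2.22 against 3.78 ± 0.803 CPM, log2 1.52, SE 0.20, adjusted p = 0.019), a call lost without wild type replicate 1 or Del(i9-13) replicates 1 or 3 (adjusted p up to 0.216). Lefty2, a Nodal antagonist (log2 2.16, adjusted p = 0.037), Apln (0.54, 0.03) and, lower, the transcription factor gene Bcl11a (−1.41, 0.035) were lost when any 1 of the 6 libraries was left out (adjusted p up to 0.474). The axonal adhesion gene Cntn2 (−1.37, 0.034) was lost without any library other than wild type replicate 3 and Tbc1d13 (0.69, 0.027) without any other than wild type replicate 2. Dpp3 (0.46, 0.023) was lost without wild type replicates 2 or 3 or Del(i9-13) replicates 1 or 2, and Rpsa (0.41, 0.017) without any 1 wild type library. The pseudogenes Mid1-ps1 (4.68, on chromosome Y), Tdg-ps2 (−8.32) and Rpl3-ps1 (−3.84) were also called and are uncertain, since reads may be shared with their parent genes, which was not tested. All 3 Del(i9-13) libraries expressed Y-linked genes, whereas wild type replicates 2 and 3 had high Xist.

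Among the lists that passed camera at E9.5, no member passed over all genes tested. Every list call below had an adjusted p = 0.638 with an estimated correlation. Liver bud and visceral endoderm markers were higher (adjusted p = 7.6e-07, median log2 2.92, 16 of 17 members positive, 0 adjusted over the list alone), among them Apoa4 at 5.48 and Amn at 3.45. The level of that list differed between libraries, at −0.26, 1.19 and 2.96 in Del(i9-13) and −1.61, −1.81 and −0.32 in wild type (median log2 difference from the mean). Hypoxia and glycolysis genes were higher (7.9e-07, median 0.19, 19 of 21 positive, 4 adjusted over the list alone), among them Bnip3 at 0.62 and Aldoa at 0.26. Tail bud and neuromesodermal progenitor genes were higher (2.4e-04, median 0.27, 24 of 27 positive; 2 higher and 1 lower adjusted over the list alone), with Cdx1 at 0.45 and Sall4 at 0.38. Wild type replicate 1 lay low in that list, at −0.38 against 0.02 to 0.22 in the other E9.5 libraries. Hindgut and endoderm epithelium was higher (6.7e-04, median 0.33, 15 of 18 positive, 0 adjusted over the list alone), with Krt19 at 0.48.

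Another 4 lists went the other way at E9.5. Spinal cord and neuron genes were lower (6.7e-04, median −0.28, 17 of 23 negative, 6 adjusted over the list alone), with Dcx at −1.03 and Elavl3 at −0.90. Heart muscle genes (9.3e-04, median −0.74, 14 of 14 negative), with Ttn at −1.88 and Tnnt2 at −0.74, were lower as well. So were Hox groups 9 to 13 outside HoxB (0.011, median −0.23, 14 of 16 negative), with Hoxa11 at −0.74, and endothelium (0.036, median −0.12, 12 of 14 negative), with Eng at −0.20. Adjusted over the list alone, heart muscle and Hox groups 9 to 13 each kept 1 member and endothelium 0. The spinal cord call was lost without Del(i9-13) replicate 3 (adjusted p = 0.144) and the heart call without wild type replicate 3 (0.101). With an Xist covariate the direction of the Hox list turned (adjusted p = 0.370). The Hox call was lost without wild type replicates 2 or 3 or Del(i9-13) replicate 3, and the endothelium call without wild type replicates 2 or 3 or Del(i9-13) replicates 1 or 2 (adjusted p up to 0.184 for both).

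At E10.5, Del(i9-13) against wild type asked the same question a day later. Of 17202 genes tested, 84 passed, 42 higher and 42 lower. Pop4, which encodes a subunit of RNase P, rose from 29.9 ± 1.51 to 88.9 ± 12.2 CPM (log2 1.57, SE 0.11, adjusted p = 6.4e-06). Lower were the meiotic helicase gene Hfm1 (log2 −4.02, SE 0.39, adjusted p = 0.00018; 0.223 ± 0.0768 against 3.74 ± 0.82 CPM), the clock gene Arntl2 (−2.21, SE 0.32, adjusted p = 0.0046; 0.473 ± 0.224 against 2.19 ± 0.44), and Qrich2 (−2.93, adjusted p = 0.0043). These calls held whichever library was left out and under every alternative in which the gene was tested. Pop4 and Qrich2 did not follow the deletion, since Hoxb13hd against wild type also called Pop4 higher and Qrich2 lower. Pop4 was called lower in Del(i9-13):Hoxb13hd against Hoxb13hd, and Pop4, Hfm1 and Arntl2 were called in the interaction with hd. Hfm1, Arntl2 and Qrich2 were not tested in 2, 2 and 3 of the 18 alternatives. Of the 24 sterol genes, a list chosen after the data were seen, 22 had negative values, with a median log2 of −0.14.

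Other calls in E10.5 Del(i9-13) were less stable. Eef2k, the kinase of elongation factor eEF2 (−1.15, 0.016; 19.7 ± 1.96 against 43.8 ± 3.44 CPM), the transporter gene Abca5 (−0.90, 0.026) and Gchfr (1.76, 0.045) were lost without any library other than Del(i9-13) replicate 1. The muscle gene Ankrd2 (2.65, 0.026) was lost without any 1 wild type library or Del(i9-13) replicate 3, and the MHC gene H2-Q7 (−1.54, 0.045), whose paralogs may share reads, without any 1 wild type library or Del(i9-13) replicate 2. Gsg1 (−1.54, 0.041) and Pxmp2 (−0.84, 0.05) were lost when any 1 library was left out (adjusted p up to 0.298 over these genes and alternatives). Of the 84 calls, 20 were pseudogenes. The number of calls was 40 without wild type replicate 2, 52 without wild type replicate 3, 285 without Del(i9-13) replicate 1, 48 without Del(i9-13) replicate 2 and 52 without Del(i9-13) replicate 3. Head and brain genes, in embryos without the head, were higher as a list (camera adjusted p = 0.0038, adjusted p = 0.113 with an estimated correlation, median 0.30, 11 of 11 tested members positive). Of its members 0 passed over all genes tested and 3 adjusted over the list alone, with Lhx2 at 0.49 and Emx2 at 0.56. The call was lost without Del(i9-13) replicate 1 (0.0615).

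In Del(i9-13):Hoxb13hd against wild type, which asked what the deletion and hd changed together, 69 genes passed, 33 higher and 36 lower. Hddc3, a phosphohydrolase gene, rose from 6.53 ± 0.78 to 26.6 ± 5.47 CPM (log2 2.03, SE 0.16, adjusted p = 4.3e-05). Hjurp, the chaperone of centromeric histone CENP-A, fell (−0.87, adjusted p = 0.0035; 148 ± 3.15 against 270 ± 50.3). These calls held whichever library was left out and, for Hjurp, under every alternative other than a minimum log2 change of 1. P4ha3, a prolyl hydroxylase subunit of collagen synthesis (1.78, 0.016; 7.27 ± 0.494 against 2.12 ± 0.214), Lrrc51 (1.65), Rwdd3 (1.17), and, lower, the small nucleolar RNA host gene Snhg1 (−0.93, 0.029; 77.6 ± 5.49 against 148 ± 13.3), Il18bp (−1.02) and H2-T24 (−2.43, an MHC paralog) were lost when any 1 library was left out (adjusted p up to 0.199 over the alternatives). Cldn34c1, with 0 counts in Del(i9-13):Hoxb13hd, was at least 38.0-fold lower than wild type against the floor over the group (adjusted p = 0.047), and was lost in the same way. Map6 (0.82, 0.014), Slc26a11 (1.16), Snhg6 (−0.71), Qrich2 (−2.83), Tcea1 (−0.65) and Eef2k (−1.09) were lost in 3 to 5 of the 6 fits that leave out 1 library, among them those without wild type replicates 1 and 2 (up to 0.173). Calls numbered 20, 14 and 30 without wild type replicates 1, 2 and 3, and 18, 41 and 20 without Del(i9-13):Hoxb13hd replicates 1, 2 and 3.

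Head and brain genes were higher in Del(i9-13):Hoxb13hd than in wild type as a list, with all 11 tested members positive and a median log2 of 0.53 (camera adjusted p = 8.1e-05, adjusted p = 0.034 with an estimated correlation, which kept the call). The embryos had no head, and members removed by the count filter were not tested, so that the list's name is not evidence of head tissue. Lhx2, a homeobox gene of the forebrain and limb bud, passed (log2 0.53, adjusted p = 0.044; 27.5 ± 0.85 against 19 ± 2.26 CPM), though not when any 1 library was left out (up to 0.173), and 4 members passed adjusted over the list alone. Emx2 was at 0.83 and Barhl1 at 1.43. The other list calls were lost with an estimated correlation. Surface ectoderm was higher (camera adjusted p = 0.0016, adjusted p = 0.642 with an estimated correlation, median 0.28, 11 of 12 positive, 2 adjusted over the list alone), with Krt15 at 0.90. Wnt targets were higher (camera adjusted p = 0.0016, adjusted p = 0.311 with an estimated correlation, median 0.23, 14 of 15 positive), with Axin2 at 0.17, and so were limb bud genes (camera adjusted p = 0.0028, adjusted p = 0.311 with an estimated correlation, median 0.23, 14 of 14 positive), with Lmx1b at 0.44, each with 0 members adjusted over the list alone. Tail bud genes (camera adjusted p = 0.035, adjusted p = 0.997 with an estimated correlation, median 0.14, 21 of 27 positive, 1 adjusted over the list alone) lost their call without Del(i9-13):Hoxb13hd replicates 1 or 2 and turned direction without wild type replicate 3 (adjusted p = 0.940). Heart muscle genes were lower (camera adjusted p = 0.0028, adjusted p = 0.997 with an estimated correlation, median −1.96, 17 of 17 negative, 0 adjusted over the list alone), a call that rested on wild type replicate 3 (adjusted p = 0.534 without it). Myh7 was at 67.1 ± 98.6 CPM in wild type and 9.11 ± 2.2 in Del(i9-13):Hoxb13hd. Of the other lists, Hoxd4 was called lower (−0.46, adjusted p = 0.046), also not without any 1 library (up to 0.230).

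Hoxb13hd against wild type asked how embryos with hd alone differed, and gave the largest number of calls against wild type, 517, with 244 higher and 273 lower. Hoxb13 itself was low in both groups, at 0.0510 ± 0.0529 CPM in Hoxb13hd and 0.434 ± 0.607 in wild type. The calls are not assigned to hd, and other differences between these groups are weighed below. Genes of the tail bud and neuromesodermal progenitors rose as a list, with 25 of 27 members positive and a median log2 of 0.68 (camera adjusted p = 1.1e-12, adjusted p = 0.225 with an estimated correlation). Of these members 9 passed over all genes tested and 21 adjusted over the list alone. Sall4 went from 102 ± 13.4 to 156 ± 6.71 CPM (log2 0.62, adjusted p = 0.02), Lin28a, a regulator of developmental timing, from 191 ± 45.8 to 306 ± 28 (0.68, 0.02), Ptk7 from 214 ± 8.02 to 286 ± 2.89 (0.42, 0.012) and Notum, a Wnt antagonist, from 6.44 ± 0.637 to 10.45 ± 0.886 (0.70, 0.014). Cdx1 (1.16, 0.035), Sp5 (1.07, 0.042), Wnt3a (0.95, 0.049), Fgf8 (0.79, 0.037) and Sp8 (0.53, 0.031) were the others. The list kept its call whichever library was left out (adjusted p up to 3.2e-10). Its level was 0.19, 0.53 and 0.57 in the Hoxb13hd libraries and −0.14, 0.15 and −0.45 in wild type. Beside it, Hox groups 10 to 13 outside HoxB lay at 0.28, 0.53 and 0.50 in Hoxb13hd and 0.40, 0.02 and −0.24 in wild type, and the pair of hindlimb genes Tbx4 and Pitx1 at 0.42 to 0.67 against −0.11 to −0.01.

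Signalling and segmentation genes moved with the tail bud list in Hoxb13hd. Wnt targets rose (camera adjusted p = 5.9e-06, adjusted p = 0.168 with an estimated correlation, median 0.35, 12 of 15 positive), with 6 called and 8 adjusted over the list alone, among them Axin2 (0.35, 0.017; 97.2 ± 8.21 against 76.2 ± 1.34 CPM), Lef1 (0.68, 0.044) and Apcdd1 (0.57, 0.017). Presomitic mesoderm and segmentation clock genes rose (camera adjusted p = 7.5e-05, adjusted p = 0.225 with an estimated correlation, median 0.30, 20 of 25 positive), with 3 called and 5 adjusted over the list alone. These were the Notch ligand gene Dll1 (0.41, 0.027; 69.1 ± 7.15 against 51.9 ± 4.21), the clock gene Hes7 (2.04, SE 0.46, adjusted p = 0.037; 2.76 ± 0.491 against 0.670 ± 0.338) and Pcdh8 (0.85, 0.046). Fgf targets rose (camera adjusted p = 0.0022, adjusted p = 0.189 with an estimated correlation, median 0.21, 10 of 11 positive), with Dusp4 called (0.33, 0.032) and 3 adjusted over the list alone. Surface ectoderm rose (camera adjusted p = 4.7e-05, adjusted p = 0.225 with an estimated correlation, median 0.51, 11 of 12 positive), with Trp63 (0.70, 0.024), Esrp1 (0.49), Krt15 (1.09) and Grhl2 (0.53) called and 6 adjusted over the list alone. HoxB genes rose (camera adjusted p = 0.0078, adjusted p = 0.225 with an estimated correlation, median 0.24, 10 of 12 positive; 4 adjusted over the list alone). Of them Hoxb1 passed (0.93, SE 0.15, adjusted p = 0.0098; 10.01 ± 1.62 against 5.25 ± 0.719), though not without wild type replicate 1 (0.0506).

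Hox groups 9 to 13 outside HoxB were also higher in Hoxb13hd (camera adjusted p = 0.012, adjusted p = 0.610 with an estimated correlation, median 0.46, 15 of 17 positive; 2 adjusted over the list alone), with Hoxd9 called (0.59, 0.012; 22.2 ± 2.04 against 14.8 ± 1.24 CPM). That list call was lost without wild type replicate 3 or Hoxb13hd replicates 2 or 3 (adjusted p up to 0.117). Hypoxia and glycolysis genes were higher (camera adjusted p = 0.0022, adjusted p = 0.395 with an estimated correlation, median 0.29, 13 of 20 positive; 8 adjusted over the list alone), with Pfkl (0.48, 0.016) and Ndrg1 (0.58, 0.04) called, but not as a list without Hoxb13hd replicate 3 (0.0785). Extraembryonic tissue genes were higher (camera adjusted p = 0.031, adjusted p = 0.398 with an estimated correlation, median 0.36, 6 of 7 positive, 1 adjusted over the list alone), lost without wild type replicates 2 or 3 or Hoxb13hd replicates 1 or 2 (up to 0.454).

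Somite, liver and heart lists were lower in Hoxb13hd. Somite derivatives fell (camera adjusted p = 0.027, adjusted p = 0.350 with an estimated correlation, median −0.12, 12 of 17 negative; 1 higher and 5 lower adjusted over the list alone), with Nkx3-2, a gene of the sclerotome, called (−0.72, 0.039; 2.24 ± 0.284 against 3.71 ± 0.301 CPM), but not without Hoxb13hd replicate 3 (0.116). Liver bud and visceral endoderm fell (camera adjusted p = 6.2e-04, adjusted p = 0.419 with an estimated correlation, median −1.82, 16 of 17 negative, 0 adjusted over the list alone), with Afp at 54.8 ± 36.3 against 234 ± 136 CPM. Heart muscle fell (camera adjusted p = 7.2e-04, adjusted p = 0.610 with an estimated correlation, median −1.69, 17 of 17 negative, 0 adjusted over the list alone), but not without wild type replicate 3 (0.0898). From lists that did not pass, the neuronal genes Dcx (−1.43, 0.039; 21.2 ± 7 against 57.0 ± 22) and Elavl4 (−0.62, 0.04) were lower, as was Trp53inp1 (−0.61), and Krt19 (0.64), Msx1 (0.61), Ret (0.63) and Dlx2 (0.92) were higher. By size of change, the receptor genes Agtr2 (−4.26, 0.012) and Gria2 (−1.81, 0.017), the calcium-binding gene Calb1 (−1.71, 0.031), Serpina10 (−2.45), Nwd2 (−2.07), Tmem163 (−1.98), Akr1c14 (−1.98), Thsd7b (−1.70), H2-T24 (−3.03) and Qrich2 (−1.95) were lower. The haemoglobin genes Hba-a2 (8.87, SE 1.74, adjusted p = 0.04; 77.0 ± 9.57 against 0.158 ± 0.0871 CPM) and Hbb-bh0 (5.45, 0.02; 34.4 ± 7.57 against 0.785 ± 0.275), whose paralogs may share reads, and Ankrd2 (2.05) were higher.

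The calls in Hoxb13hd depended on few libraries. Their number was 57 and 110 without wild type replicates 1 and 3 and 51 and 71 without Hoxb13hd replicates 2 and 3, and ran from 51 to 676 over the 6 libraries left out in turn. Apart from pseudogenes, the calls named in Hoxb13hd were lost without some of these 4 libraries, with an adjusted p up to 0.328 for Ndrg1 and, among tail bud genes, up to 0.183 for Sp5. Those of Hba-a2, Ankrd2, Lef1, Pcdh8 and Nkx3-2 were lost when any 1 of the 6 libraries was left out (up to 0.178).

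**Figure D3:**
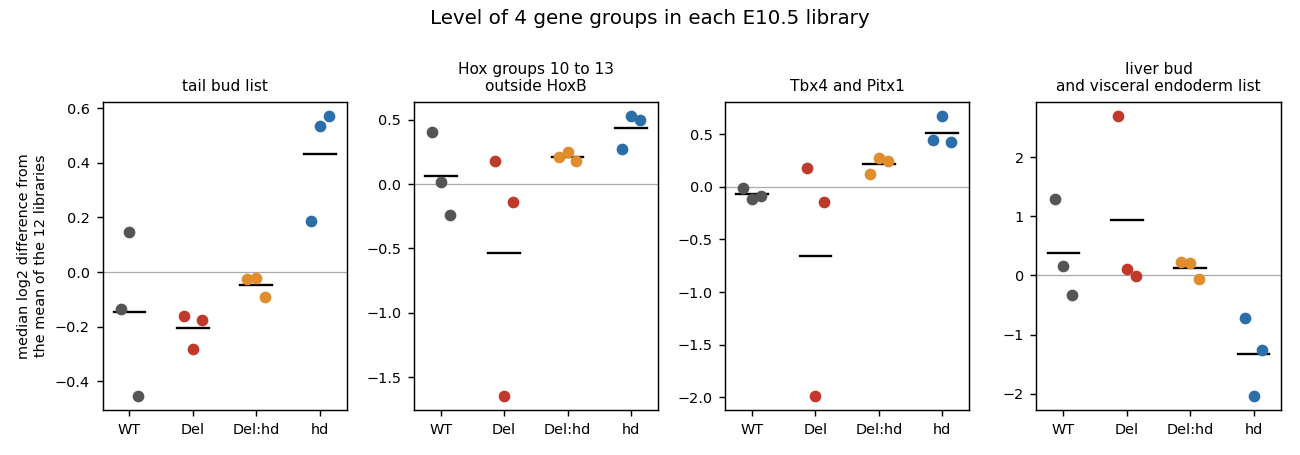
Median log2 difference from the mean of the 12 E10.5 libraries for each library (points) and group mean (bars), for tail bud genes, Hox groups 10 to 13 outside HoxB, Tbx4 with Pitx1, and liver bud with visceral endoderm. The tail bud level lies at 0.19 to 0.57 in Hoxb13hd, and Del(i9-13) replicate 2 stands apart at −1.65 for the Hox groups and −1.99 for Tbx4 with Pitx1.

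Del(i9-13) against Del(i9-13):Hoxb13hd asked what hd changed when the deletion was present, and 156 genes passed, 62 higher and 94 lower in Del(i9-13). Pop4 was higher (88.9 ± 12.2 against 30.5 ± 3.2 CPM, log2 1.54, adjusted p = 1.2e-05), as were the histone gene H4f16 (1.39, 0.00057; 635 ± 147 against 242 ± 23.5), H2-T24 (2.84, 0.0062) and H2-Bl (2.75, 0.0049), the last 3 with paralogs that may share reads. Hddc3 (−1.73, SE 0.15, adjusted p = 0.0001; 8.01 ± 0.868 against 26.6 ± 5.47), Hfm1 (−3.58, 0.00045) and H2-Q7 (−1.89, 0.0086) were lower. Axin2, a direct Wnt target, was lower as well (−0.42, SE 0.06, adjusted p = 0.0062; 63.8 ± 2.12 against 85.6 ± 1.46). These calls held whichever library was left out, but under other alternatives the adjusted p reached 0.102 for H2-Q7 and 0.0508 for Hfm1 and Axin2. The 24 sterol genes, a list chosen after the data were seen, had a median log2 of −0.16.

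Less stable in Del(i9-13) against Del(i9-13):Hoxb13hd were Trmo (1.37, 0.0083), lost without Del(i9-13):Hoxb13hd replicate 1 (0.0609), P4ha3 (−1.62, 0.013), lost without Del(i9-13) replicate 2 or Del(i9-13):Hoxb13hd replicate 2 (up to 0.059), and Arntl2 (−1.92, 0.012), lost without Del(i9-13) replicate 3 or Del(i9-13):Hoxb13hd replicates 1 or 3 (up to 0.0746). Grik3 (−1.49), Aldh3b2 (−1.46) and Tac2 (−1.25) were lost without replicates 2 or 3 of either group. Gsg1 (−1.5), Srp54a (3.03) and Cldn34c1 (84 against 0 counts, at least 28.2-fold higher against the floor over the group; adjusted p = 0.044) were lost without any library other than Del(i9-13) replicate 1 (adjusted p up to 0.188 over these genes). Calls numbered 1453, 72 and 67 without Del(i9-13) replicates 1, 2 and 3 and 72, 84 and 58 without Del(i9-13):Hoxb13hd replicates 1, 2 and 3.

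As lists, Wnt targets were lower in Del(i9-13) than in Del(i9-13):Hoxb13hd (camera adjusted p = 9.6e-04, adjusted p = 0.456 with an estimated correlation, median −0.25, 12 of 15 negative). Of them 1 passed over all genes tested, Axin2, and 5 adjusted over the list alone. Hox groups 9 to 13 outside HoxB (camera adjusted p = 0.015, adjusted p = 0.847 with an estimated correlation, median −0.40, 15 of 17 negative, 0 adjusted over the list alone), with Hoxc13 at −1.47 and Hoxd12 at −0.81, were lower too. So were tail bud genes (camera adjusted p = 0.015, adjusted p = 0.847 with an estimated correlation, median −0.25, 23 of 27 negative, 1 adjusted over the list alone), with Ptk7 called (−0.34, 0.043; 210 ± 20.6 against 267 ± 10.7 CPM, lost without any library other than Del(i9-13) replicate 1, up to 0.207). Both calls were lost without Del(i9-13) replicate 2 or Del(i9-13):Hoxb13hd replicate 2 (adjusted p up to 0.534 and 0.0807). Limb bud genes (camera adjusted p = 0.027, adjusted p = 0.776 with an estimated correlation, median −0.17, 12 of 14 negative, 0 adjusted over the list alone), with Msx1 at −0.32, lost their call without Del(i9-13):Hoxb13hd replicate 2 (0.0807). Beside these groups, Del(i9-13) replicate 2 lay at −1.65 in Hox groups 10 to 13 outside HoxB, where the other 11 E10.5 libraries ran from −0.24 to 0.53, and at −1.99 in Tbx4 with Pitx1.

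Del(i9-13):Hoxb13hd against Hoxb13hd asked what the deletion changed in embryos that carry hd, and 165 genes passed, 116 higher and 49 lower in Del(i9-13):Hoxb13hd. Tail bud genes were lower, with 25 of 27 members negative and a median log2 of −0.48 (camera adjusted p = 3.4e-09, adjusted p = 0.348 with an estimated correlation), whichever library was left out (up to 4.7e-07). Of them Lin28a (−0.79, 0.017; 177 ± 6.1 against 306 ± 28 CPM) and Sp8 (−0.55, 0.045) passed over all genes tested and 17 adjusted over the list alone, with Cdx1 at −1.04. Presomitic mesoderm genes (camera adjusted p = 0.0012, adjusted p = 0.348 with an estimated correlation, median −0.27, 20 of 25 negative; 3 adjusted over the list alone) were lower, with Dll1 at −0.36 and Hes7 at −1.92, as were Wnt targets (camera adjusted p = 0.015, adjusted p = 0.348 with an estimated correlation, median −0.18, 12 of 15 negative; 1 higher and 5 lower adjusted over the list alone). Hypoxia genes were lower (camera adjusted p = 0.0012, adjusted p = 0.382 with an estimated correlation, median −0.25, 16 of 20 negative; 7 adjusted over the list alone), with Pfkl at −0.36. HoxB genes were lower as a list (camera adjusted p = 0.013, adjusted p = 0.348 with an estimated correlation, median −0.25, 9 of 12 negative; 1 higher and 4 lower adjusted over the list alone), with Hoxb9 called lower and Hoxb13 higher, so that the mean log2 over the list was 0.31. Macrophage and other blood cell genes (camera adjusted p = 0.0012, adjusted p = 0.348 with an estimated correlation, median 0.89, 10 of 11 positive; 2 adjusted over the list alone), with Cx3cr1 at 1.64, and liver bud with visceral endoderm (camera adjusted p = 0.0012, adjusted p = 0.433 with an estimated correlation, median 1.53, 13 of 17 positive, 0 adjusted over the list alone), with Trf at 1.96, were higher. Without Hoxb13hd replicate 3 the hypoxia and Wnt calls were lost (0.0515 for both), and without Del(i9-13):Hoxb13hd replicate 3 the HoxB call (0.0603). The tail bud level was −0.03, −0.02 and −0.09 in Del(i9-13):Hoxb13hd and 0.19, 0.53 and 0.57 in Hoxb13hd. That of liver bud with visceral endoderm was 0.24, 0.20 and −0.06 against −0.71, −2.03 and −1.26. An earlier stage or a larger share of caudal tissue in the Hoxb13hd embryos, weighed below, was not separated from an effect of the deletion in these lists.

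Among single genes in that comparison, Snhg1 was lower (77.6 ± 5.49 against 189 ± 31.7 CPM, log2 −1.29, SE 0.16, adjusted p = 0.0033) and the actin-associated gene Palmd higher (1.84, adjusted p = 0.0045; 2.39 ± 0.381 against 0.659 ± 0.209), whichever library was left out, although Palmd reached an adjusted p of 0.0657 under another alternative. Agtr2 (4.30, 0.015; 1.70 ± 0.367 against 0.0782 ± 0.0714) was higher, but not without Del(i9-13):Hoxb13hd replicate 1 or Hoxb13hd replicates 2 or 3 (up to 0.0777). Also higher were the coagulation genes Plg (2.67), Serpind1 (2.42) and Serpinc1 (1.94), made by the liver, and Calb1 (2.06), Uts2b (2.48), Nwd2 (1.86), Prdm16os (1.86), Hmx1 (1.79), Stmn2 (1.11), Robo4 (0.71) and Lhx2 (0.51). Lower were Hes3 (−1.79), Prtg (−0.98, 0.02; 175 ± 10.1 against 346 ± 55.6), Nlrp6 (−2.06), Gchfr (−1.65), Tmem35b (−1.25), Trmo (−1.13), Hoxaas3 (−1.06), Sox1 (−0.77) and Hoxd4 (−0.52). The calls of these genes, of Lin28a and of Sp8 were lost in 4 to 6 of the 6 fits that leave out 1 library, with an adjusted p up to 0.177 over the alternatives. Calls numbered 38, 43 and 51 without Del(i9-13):Hoxb13hd replicates 1, 2 and 3 and 412, 36 and 39 without Hoxb13hd replicates 1, 2 and 3.

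The deletion effects with and without hd shared few genes. Gm53, in the deleted interval, was left out of these overlaps. Of the other 83 genes called in Del(i9-13) against wild type, 31 changed in the same direction in Del(i9-13):Hoxb13hd against Hoxb13hd (37.3%, exact 95% interval 27.0 to 48.7), against 50.1% of all genes. Taken the other way, of 164 genes called in Del(i9-13):Hoxb13hd against Hoxb13hd, 97 had the same direction in Del(i9-13) against wild type (59.1%, 51.2 to 66.7), so that the share lay below or above that of all genes with the choice of genes. Hoxb13 was called higher in both, and Hoxb9, Abca5, Noc2l and Gm5182 lower in both, against 0.283 and 0.114 expected if independent. Another 13 were called in opposite directions, among them Pop4, H4f16, Gchfr, Banp, Eif3j2 and Pcna-ps2. Between stages, 60 of 75 genes called at E10.5 and tested at both stages had the same sign at E9.5 (80.0%, 69.2 to 88.4) and 41 of 55 called at E9.5 had the same sign at E10.5 (74.5%, 61.0 to 85.3), against 59.2% of all genes. Besides Gm53, called at both stages were Hoxb13 and Chl1, higher, and Hoxb9 and Scd1, a fatty acid desaturase gene, lower. The genes named in these overlaps outside the naming rule were chosen after their values were seen.

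All 3 mutant genotypes at E10.5 shared calls against the same wild type libraries. Slc9a3r1, Endov and the pseudogenes Rps15a-ps5, Rps15a-ps6, Rps15a-ps8, Gm7666 and Mrpl27-ps were higher in all 3, and Eef2k, Qrich2, Banp and D030028A08Rik were among those lower, names chosen after the values were seen. Pairs of mutants shared 9 higher and 6 lower calls (Del(i9-13) and Del(i9-13):Hoxb13hd), 24 and 6 (Del(i9-13) and Hoxb13hd) and 21 and 18 (Del(i9-13):Hoxb13hd and Hoxb13hd). The covariance of effects was 0.0813, 0.0986 and 0.111 for these pairs against means of 0.0505, 0.05002 and 0.0505 and highest values of 0.0658, 0.0608 and 0.0655 in 20 simulations in which the shared wild type libraries were the only link. Their correlation was 0.376, 0.368 and 0.456 against 0.497, 0.487 and 0.486 in the simulations, and the share of genes with the same sign 60.2%, 58.4% and 67.3% against 66.7%, 66.6% and 66.7%. The covariance thus lay above every simulation, more than the shared wild type libraries gave at the spread simulated, which was 1 value per gene for all groups. A larger spread of the wild type libraries was not simulated, and controls of 3 cannot be divided between the comparisons, so that effects shared by the mutants remain 1 of the explanations. The pseudogene Rps15a-ps8, with 1 count over wild type, had ratios of 1091 (195 to 43130.3) in Del(i9-13), 988 (177 to 39081.5) in Del(i9-13):Hoxb13hd and 875 (157 to 34595.8) in Hoxb13hd. Within E9.5, however, Rps15a-ps8 was at 21.3 ± 7.66 CPM in wild type and 19.7 ± 6.53 in Del(i9-13). It was thus not off in every wild type group, and the E10.5 difference may lie in the E10.5 wild type libraries. Rps15a-ps6 had log2 values of 7.41, 7.17 and 7.0 and Rps15a-ps5 of 4.60, 4.41 and 4.97. In limma on log2(FPKM + 0.1) without a filter, Rps15a-ps6 fell short of the threshold in all 3, and Rps15a-ps5 did so in Del(i9-13):Hoxb13hd and turned direction in Del(i9-13) (−0.0168) and Hoxb13hd (−0.91). Pcna-ps2 (5.79 and 6.0) and Eif3j2 (5.78 and 6.13), a close copy of Eif3j1, were higher than wild type in Del(i9-13) and Hoxb13hd, as was Npm3-ps1 in Hoxb13hd, which turned to −0.61 in that alternative. In Del(i9-13), Rps18-ps6 was also higher (11.10). The levels of all of these are uncertain, since reads may be shared with parent genes, which was not tested.

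The interaction of deletion and hd at E10.5 gave 90 calls, 43 higher and 47 lower. For these genes the difference between groups with and without the deletion was called as not the same with and without hd. Pseudogenes made up 22 of the calls (24.4%, against 2.84% of genes tested). Pcna-ps2 followed neither allele, at 16.3 CPM in Del(i9-13) and 18.8 in Hoxb13hd against 0.287 in wild type and 0.164 in Del(i9-13):Hoxb13hd. Whether the calls come from deletion and hd or from other differences between the groups, such as genetic background, was not tested. The tail bud list differed (camera adjusted p = 5.7e-05, adjusted p = 0.629 with an estimated correlation, median 0.60, 25 of 27 positive; 0 members over all genes and 1 adjusted over the list alone), as did surface ectoderm (camera adjusted p = 0.032, adjusted p = 0.629 with an estimated correlation, median 0.37, 10 of 12 positive; 3 adjusted over the list alone). Hoxb13 (log2 −3.18, SE 1.41, adjusted p = 0.42) and Hoxb9 (−0.04, adjusted p = 0.94) did not pass, and without wild type replicate 1 Hoxb13 was at −0.93 (−4.09 to −0.93 over the libraries left out). Without wild type replicates 1 and 3 calls numbered 47 and 45, without Del(i9-13) replicates 1 and 3 they numbered 174 and 50, without Del(i9-13):Hoxb13hd replicates 1, 2 and 3 they numbered 40, 43 and 48, and without Hoxb13hd replicate 3 they numbered 53. The surface ectoderm call was lost without wild type replicates 2 or 3, Del(i9-13) replicate 1 or Hoxb13hd replicates 2 or 3 (up to 0.128). The tail bud interaction includes the Hoxb13hd libraries, for which an earlier stage and a larger share of caudal tissue stay open, as weighed below.

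Between stages the deletion effect was called as different for 8 of 17670 genes, all with a larger value at E10.5, a number that 4 of 50 labellings reached, the real one included. Of these 5 were pseudogenes and 3 were not. Among the latter were Insig1 (log2 0.86, adjusted p = 0.048) and Rhbdl3 (0.96, adjusted p = 0.03), both of which were lower at E9.5. Hoxb13 rose by less at E10.5 than at E9.5 in the fitted values, a difference that did not pass (−4.22, SE 1.2, adjusted p = 0.44) and was −2.01 without E10.5 wild type replicate 1 (−4.80 to −2.01 over the libraries left out). Hoxb9 did not pass either (−0.31, 0.65). Both the Insig1 and the Rhbdl3 calls were lost in most fits that leave out 1 library (adjusted p up to 0.173 over the alternatives). Calls numbered 24, 20, 5, 3 and 3 without E9.5 wild type replicates 2 and 3 and Del(i9-13) replicates 1, 2 and 3. They numbered 3, 3 and 3 without E10.5 wild type replicates 1, 2 and 3 and 16, 5 and 5 without E10.5 Del(i9-13) replicates 1, 2 and 3.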

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

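The tests of caudal tissue share, mislabelled genotype, deletion effect on posterior Hox genes, liver and visceral endoderm content, and Hoxb13 activity were chosen only after the results were seen, as were the Xist covariate and the fits without Del(i9-13) replicate 2.

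The first group of results was singled out because an interaction term at E10.5 called 90 genes for a deletion effect that differed with and without hd. Other differences between the groups, such as genetic background, were not tested as a cause. Fitted log2 differences were positive for the pseudogenes Pcna-ps2 (12.55), Rps15a-ps8 (9.44), Npm3-ps1 (7.34), Rps15a-ps6 (7.24) and Rps15a-ps5 (5.17). They were also positive for Eif3j2 (12.12), Gchfr (3.41), Pop4 (2.55), H4f16 (2.50) and Tmem35b (1.95). They were negative for Rps3a3 (−17.15), Hist1h2al (−15.81), Ifi202b (−9.88), Hfm1 (−4.68), Agtr2 (−4.52), Arntl2 (−2.90), Plppr1 (−2.57), Nwd2 (−2.55), Gsg1 (−2.42) and Aldh3b2 (−2.09). Values for genes with 3 or fewer counts over a group (Rps15a-ps8, Npm3-ps1 and Ifi202b) depend on the prior count and are no bounds, and those of pseudogenes, histone genes and close paralogs are uncertain. The calls of Pcna-ps2, Eif3j2, the 3 Rps15a pseudogenes, Gchfr, Pop4, H4f16, Hfm1 and Arntl2 held in all 12 fits that leave out 1 library, and those of the other genes were lost in 5 to 11 of them (adjusted p up to 0.758 over the alternatives, for Npm3-ps1). In limma on log2(FPKM + 0.1) without a filter the interaction turned direction for Rps15a-ps5 (−1.06) and Npm3-ps1 (−0.37), and Rps15a-ps6 fell short of the threshold. As lists, tail bud genes differed by a median of 0.60 and surface ectoderm by 0.37, both with an adjusted p of 0.629 with an estimated correlation. The tail bud call held in all 12 fits that leave out 1 library (up to 0.0039), and the surface ectoderm call was lost without wild type replicates 2 or 3, Del(i9-13) replicate 1 or Hoxb13hd replicates 2 or 3 (up to 0.128).

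The second group was singled out because an interaction term called 8 genes for a deletion effect that differed between E9.5 and E10.5, a number for which chance is not excluded (4 of 50 labellings, the real one included). Among them were the pseudogenes Rps15a-ps8 (9.83), Rps15a-ps6 (7.24), Npm3-ps1 (5.91) and Rps15a-ps5 (4.59), and Rhbdl3 (0.96) and Insig1 (0.86). In limma on log2(FPKM + 0.1) without a filter Npm3-ps1 turned to −0.16 and Rps15a-ps5 to −0.40, and Rps15a-ps6 fell short of the threshold. The medians of lists that differed were −0.31 for hypoxia and glycolysis (camera adjusted p = 4.2e-09, adjusted p = 0.166 with an estimated correlation), 0.55 for head and brain (0.0020; 0.144), −0.37 for tail bud (0.0020; 0.796) and −1.68 for liver bud with visceral endoderm (0.0020; 0.796). They were 0.91 for macrophages (0.013; 0.728), −0.30 for hindgut (0.013; 0.796), −0.40 for extraembryonic tissue (0.045; 0.728) and −0.16 for HoxB (0.048; 0.561). Of their members 0 passed over all genes tested in edgeR. Hypoxia and head and brain kept their calls in all 12 fits that leave out 1 library. The tail bud call was lost without E9.5 wild type replicate 1 or E10.5 wild type replicate 2 (up to 0.169), the liver call without E9.5 Del(i9-13) replicate 3, E10.5 wild type replicate 1 or E10.5 Del(i9-13) replicates 2 or 3 (up to 0.174), and the macrophage call without E9.5 wild type replicate 1, E9.5 Del(i9-13) replicate 2 or E10.5 Del(i9-13) replicate 1 (up to 0.0981). The hindgut, extraembryonic and HoxB calls were lost in 7 to 11 of these fits (up to 0.610).

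Whether other splits of the same libraries give as many calls was counted for each comparison. For E9.5 Del(i9-13) against wild type the real split gave 58 and the highest other split 1. At E10.5 these numbers were 84 and 5 for Del(i9-13) and 69 and 2 for Del(i9-13):Hoxb13hd, each against wild type, and 517 and 2 for Hoxb13hd against wild type. They were 156 and 0 for Del(i9-13) against Del(i9-13):Hoxb13hd and 165 and 0 for Del(i9-13):Hoxb13hd against Hoxb13hd. The 10 splits of each pair are too few for a share under 0.05. For the interaction with hd, of 50 labellings with the real one included, only 1, the real one, gave as many calls as 90 (highest other 15). Random deletion labels thus rarely gave as many. Each draw reassigned the deletion labels among libraries with hd and among those without it, and so broke up the genotype groups along with the interaction. The count therefore cannot tell an interaction from other differences between the groups. For the difference between stages, 4 of 50 labellings, the real one included, gave as many as the real 8, so chance is not excluded. Among these was a draw with 92 calls, and what it separates was not tested.

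The higher tail bud genes in Hoxb13hd at E10.5 were weighed first. Lower depth of these libraries was examined by thinning every E10.5 library to 19.3 M counts. The list's median log2 was then 0.68, as without thinning, and the list still passed (camera adjusted p = 1.6e-12). Since no E10.5 library held more than 25.7 M counts and levels were scaled to library size, thinning could hardly move this median. No conclusion is drawn from it. An earlier developmental stage of these embryos stays open, since 89.9% of the genes called (461 of 513, exact 95% interval 86.9 to 92.3; 69.1% of all genes) moved in the direction of E9.5 minus E10.5 in the Del(i9-13) libraries, although stage coincides with library type there. Against it stand Hox groups 10 to 13 outside HoxB, which were higher in Hoxb13hd (median 0.46, 10 of 11 genes) but lower at E9.5 without Del(i9-13) replicate 2 (−0.41, 8 of 11; 0.09 with it). A larger share of caudal tissue stays open as well, since those Hox genes with Tbx4 (0.58) and Pitx1 (0.61) were higher by a median of 0.50 (SE 0.11, 12 of 13 genes). An effect of hd itself may add to either and was not separated from them. Hoxb13 was low in both groups, at 0.0510 CPM in Hoxb13hd and 0.434 CPM in wild type, and whether such a level allows that effect was not tested.

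The low posterior Hox transcripts of E10.5 Del(i9-13) replicate 2 were weighed second: Hox groups 10 to 13 outside HoxB lay at a median log2 of −1.44 against the other deletion libraries, with Hoxc10 at −4.71 and Hoxa13 at −3.61. A loss of caudal tissue as a whole was argued against, since the tail bud list with Tbx4 and Pitx1 had a median of −0.17 and the tail bud list alone one of −0.16 (SE 0.11, 19 of 27 below), while Tbx4 (−2.47) and Pitx1 (−1.52) were low and Hox groups 4 to 6 were at 0.03. A library without the deletion was argued against, since this library had 0 counts of Gm53 where wild type libraries had 371 to 521. Gm53 also had 0 counts over Del(i9-13):Hoxb13hd, so that it cannot tell that genotype from Del(i9-13). Pop4 was at 88.9 ± 12.2 CPM over Del(i9-13), this library included, against 30.5 ± 3.2 in Del(i9-13):Hoxb13hd. It was named from these data because the libraries of the groups did not overlap, and is no check of the label. An effect of the deletion shared by the group was argued against, since the other Del(i9-13) libraries lay at 0.10 relative to wild type and this one at −1.61. A loss limited to the hindlimb region and its neighbours stays open, as does a difference of this embryo, and neither was tested.

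The lower sterol synthesis genes in E9.5 Del(i9-13) were weighed last. For the sex of the embryos, an Xist covariate gave a median log2 of −0.68 with 24 of 24 genes lower, against −0.57 without it. Xist was low in every Del(i9-13) library but, in wild type, in replicate 1 alone, so that this value rests on that library and decides little. In the list that library lay at 0.37 and the Del(i9-13) libraries at −0.26, −0.28 and −0.31. At E10.5, where both sexes occurred in every genotype, the list's median difference between the highest and the lowest Xist level was −0.04. This argues against sex as the whole cause, though at another stage. Less liver or visceral endoderm was argued against, since markers of these were higher (median 2.92, SE 0.57, 16 of 17 genes). An effect of premature Hoxb13 may be involved and stays open: at E10.5 the genes were lower in Del(i9-13) than in Del(i9-13):Hoxb13hd (median −0.16, SE 0.066, 18 of 24 lower), at −0.18, −0.14 and −0.12 in the 3 libraries, and lower than in wild type (−0.14), whereas Del(i9-13):Hoxb13hd against Hoxb13hd was at 0.05. What hd does to the gene product is not given in the sources used here, so that this remains a hypothesis found and tested on the same data.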

How the results depend on the processing

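The Xist covariate, the fits without pseudogenes and the fits without E10.5 Del(i9-13) replicate 2 were chosen only after the results were seen. Comparisons are given in the order E9.5 Del(i9-13), then E10.5 Del(i9-13), Del(i9-13):Hoxb13hd and Hoxb13hd, each against wild type, then Del(i9-13) against Del(i9-13):Hoxb13hd, Del(i9-13):Hoxb13hd against Hoxb13hd, the interaction with hd and the difference between stages. Counts of called genes stayed within 1.5 times their reported value in 69 of 161 alternatives and moved further in 92. Named genes kept direction and side of the threshold in 6295 of 7603 values, fell short of it in 1037 and passed newly in 150. Hoxb13 kept both in 153 of 160, single lists in 377 of 540, and counts of lists stayed within 1.5 times in 57 of 92. Except where a fit used fewer libraries or genes, the cause was not tested. Depth limits genes at a few counts, such as Hoxb13 in wild type, and the spread between libraries limits the rest.

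DESeq2 called 329, 276, 326, 1240, 673, 658, 297 and 88 genes in that order. In simulation, run with DESeq2 for E9.5 and E10.5 Del(i9-13) against wild type alone, unchanged genes made up more of its calls than of those of edgeR. The simulated counts used the spread estimated by edgeR, so that they do not settle which number of calls is nearer the truth. Without a filter edgeR called 537 at E9.5, 329 in Del(i9-13):Hoxb13hd against Hoxb13hd and 15 for the stages. On FPKM with a pseudocount of 0.1, limma called 30 at E9.5, 54, 28 and 293 in the E10.5 comparisons with wild type and 2 for the stages. With a pseudocount of 1 it called 30, 52, 31 and 293 in these and 4 for the stages. Without a filter on FPKM it called 20 at E9.5, 25 in Del(i9-13):Hoxb13hd and 130 in Hoxb13hd against wild type, 42 in Del(i9-13):Hoxb13hd against Hoxb13hd, 58 for the interaction and 5 for the stages. At an absolute log2 change of at least 1 there remained 18, 43, 27, 114, 51 and 70 calls in the 6 pairs. RLE scaling gave 5 for the stages. Fits of only the groups compared gave 55, 117, 333, 76 and 317 for the 5 E10.5 pairs. With an Xist covariate there were 28 and 251 calls in Del(i9-13):Hoxb13hd and Hoxb13hd against wild type. Without pseudogenes there were 50 and 44 in Del(i9-13) and Del(i9-13):Hoxb13hd against wild type, 38 for the interaction and 0 in edgeR for the stages, where 1212 genes had an unadjusted p under 0.05 with pseudogenes included and DESeq2 called 88.

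Leaving out 1 library at a time gave 40 to 53 calls at E9.5, 40 to 285, 14 to 41 and 51 to 676 against wild type at E10.5, 58 to 1453 in Del(i9-13) against Del(i9-13):Hoxb13hd, 36 to 412 in Del(i9-13):Hoxb13hd against Hoxb13hd, 40 to 174 for the interaction and 3 to 24 for the stages. The lists that passed then numbered 5 to 9 at E9.5, 0 to 6 in Del(i9-13) against wild type, 1 to 5 in Del(i9-13) against Del(i9-13):Hoxb13hd, 7 to 15 in Del(i9-13):Hoxb13hd against Hoxb13hd, 1 to 4 for the interaction and 4 to 9 for the stages. With an estimated correlation 0, 0, 1, 0, 0, 0, 0 and 0 lists passed. With fry 1 passed at E9.5, in Del(i9-13):Hoxb13hd against wild type, in both pairs without wild type and for the stages, and 0 for the interaction. An Xist covariate gave 3 lists in Del(i9-13) against wild type.

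Same-numbered libraries of different groups deviated together weakly if at all. Their correlations ran from 0.00 to 0.14 at E9.5 (median 0.092), with 1 of 3 pairs above 0.1, and from −0.23 to 0.16 at E10.5 (median 0.060), with 3 of 18. Differently numbered libraries had medians of −0.045 at E9.5, with 1 of 6 pairs above 0.1, and 0.011 at E10.5, with 5 of 36. These few weak values do not settle whether the numbers pair the samples. A replicate block gave 4 calls for the stages and 4 lists in Del(i9-13) against wild type, and moved no other count of calls or lists by over 1.5 times.

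Hoxb13 in Del(i9-13) against wild type at E10.5 fell short of the threshold without a filter (log2 4.50, adjusted p = 0.053) and in a fit of only the groups compared (4.49, adjusted p = 0.19). In Del(i9-13):Hoxb13hd against wild type it fell short with an Xist covariate (4.60, adjusted p = 0.053) and with only the groups compared (4.69, adjusted p = 0.067), and ran from 4.16 to 6.95 without 1 library, the call being lost without wild type replicate 2 (4.27). In Del(i9-13) against Del(i9-13):Hoxb13hd it ran from −0.40 to 0.0587, the last without Del(i9-13) replicate 2. Without E10.5 wild type replicate 1 it was at −0.72 in Hoxb13hd against wild type, −0.93 for the interaction and −2.01 for the difference between stages. On FPKM with a pseudocount of 1 its difference between stages passed (−2.17, adjusted p = 0.014). In limma on log2(FPKM + 0.1) without a filter, which differs from edgeR on counts in unit, model and filter, the sign of pseudogenes turned, with Rps15a-ps5 at −0.0168 in Del(i9-13) and −0.91 in Hoxb13hd against wild type, −1.06 for the interaction and −0.40 for the stages, and Npm3-ps1 at −0.61 in Hoxb13hd against wild type, −0.37 for the interaction and −0.16 for the stages. The direction of Hox groups 9 to 13 outside HoxB turned at E9.5 with the Xist covariate (adjusted p = 0.370), and that of tail bud genes in Del(i9-13):Hoxb13hd against wild type without wild type replicate 3 (0.940; adjusted p from 5.7e-05 to 0.940 without 1 library). Fisher's exact p for calls near Hoxb13, with HoxB genes and Gm53 counted among the genes outside, was 0.0337 and 0.0277 within 200 kb in Del(i9-13) and Del(i9-13):Hoxb13hd against wild type. Within 1 Mb it was 7.1e-04, 4.0e-04 and 0.0222 in the 3 comparisons with wild type, 0.293 in Del(i9-13):Hoxb13hd against Hoxb13hd and 0.0152 for the interaction.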

Other observations

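The genes named here and the description of Xist levels were chosen after the values were seen. Of the 29 gene lists, 11 passed camera in no comparison. The smallest adjusted p were 0.0646 for neural crest and for cell cycle, 0.0767 for Hox groups 1 to 8 outside HoxB and for notochord with floor plate, 0.102 for sex-linked genes, 0.124 for primitive erythroid cells, 0.133 for retinoic acid, 0.138 for p53 and cell death, 0.160 for dissection stress, 0.208 for mitochondrially encoded genes and 0.326 for intermediate mesoderm with kidney.

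Both sexes occurred in every E10.5 genotype but not in E9.5 Del(i9-13). Xist was high in E9.5 wild type replicates 2 and 3, and at E10.5 in wild type replicate 2, Del(i9-13) replicates 1 and 3, Del(i9-13):Hoxb13hd replicates 2 and 3 and Hoxb13hd replicate 1. The share of genes whose groups did not overlap was 18.9% at E9.5, 13.0%, 21.5% and 25.4% for Del(i9-13), Del(i9-13):Hoxb13hd and Hoxb13hd against wild type, 20.3% for Del(i9-13) against Del(i9-13):Hoxb13hd and 22.6% for Del(i9-13):Hoxb13hd against Hoxb13hd, where chance gives 10%. In the liver bud and visceral endoderm list E10.5 Del(i9-13) replicate 1 stood at a median log2 difference of 2.7 from the mean of the 12 libraries, with the other 11 between −2.03 and 1.29.

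Some pseudogenes were on in some libraries and off in others within a genotype, names chosen after their values were seen. Rps3a3 was at 138 and 120 CPM in E10.5 wild type replicates 2 and 3 and at 133 to 150 CPM in Del(i9-13):Hoxb13hd, but at 0.181 CPM in wild type replicate 1 and at 0.120 to 0.633 CPM in Del(i9-13) and Hoxb13hd. Hist1h2al followed the same pattern, at 125 and 104 CPM in wild type replicates 2 and 3 and 0.499 in replicate 1. At E9.5, wild type replicate 3 stood apart, with Rps3a3 at 295 CPM against 0.571 to 0.83 in the other 5 libraries and Rps18-ps6 at 0.696 CPM against 150 to 313. At E10.5 Rps18-ps6 was at 98.04 to 285 CPM in Del(i9-13) and at 0.233 CPM or less in the other 9 libraries. Of the calls, pseudogenes made up 6 at E9.5, 20, 10 and 29 in Del(i9-13), Del(i9-13):Hoxb13hd and Hoxb13hd against wild type, 21 and 13 in the other E10.5 pairs, 22 for the interaction with hd and 5 for the difference between stages. Whether these libraries differ in genetic background is not given in the sources used here, and no test of it was made.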
